A study of Mus musculus with 2 samples.

How the data were processed

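The series measured mature microRNAs by small RNA sequencing in cultured vascular smooth muscle cells. Per the labels, the cells were isolated from thoracic aortas of male mice aged 10 to 12 weeks and grown in DMEM/F-12 with 10% fetal bovine serum. The db/db mouse lacks a working leptin receptor, becomes obese and develops type 2 diabetes, and the heterozygous db/+ mouse was the control. RNA was extracted on silica columns that retain small RNA, and libraries followed a standard Illumina protocol, per the labels' protocols. There were 2 libraries, 1 per group, and how many mice each culture pooled was not given in the sources used here.

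The submitters' processing notes name Novoalign, edgeR and the mouse assembly mm10, with no versions or roles. Read trimming, mismatch limits, the microRNA catalogue and the treatment of reads that match several microRNAs were not given in the sources used here. Per the file headers, the authors deposited raw read counts and TMM-normalized reads for 1909 mature microRNAs in each library. TMM (trimmed mean of M values) is a scaling that assumes most features do not differ. The deposited normalized reads were whole numbers, so this column was treated as a score and entered only 1 alternative scaling. In the db/+ library they equalled the raw count multiplied by 0.939 and rounded, apart from 21 of 881 detected microRNAs that were off by 1 read. In the db/db library the factor was 1.06 (1.0646 before rounding), and 20 of 833 were off by 1 read, so some deposited raw counts may themselves have been rounded, by less than 1 read.

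Totals were 25915732 counts in the db/+ library and 24295112 in the db/db library. A count of 0, taken to allow up to 3 counts, allowed 0.116 CPM (counts per 1e6 microRNA counts) in db/+ and 0.123 in db/db. Among microRNAs with at least 50 counts in a library, 11 groups covering 24 names had identical counts in both libraries, for example miR-199a-3p and miR-199b-3p, which share a mature sequence. Such reads stood on several names. Let-7 members and other near-identical microRNAs may also share reads, so values of their single members are uncertain.

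Counts were scaled to the total of all mature microRNA counts of the library and given as CPM. The ratio of the db/db library over the db/+ library carries an exact conditional (Clopper-Pearson) 95% interval. Reads are PCR copies without molecular identifiers, so intervals and floors cover counting error only and say nothing of variation between mice or cultures. With 1 library per group there were no residual degrees of freedom, so the quasi-likelihood test of edgeR could not be fitted and no p-value was computed. MicroRNAs were instead counted by a size rule, a ratio of at least 2 or of at most 0.5 with at least 50 counts in at least 1 library. Log2 ratios had 0.5 counts added.

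The 20 lists of microRNAs were fixed before the data were examined. They covered the smooth muscle contractile programme, growth and migration, vascular inflammation and diabetes, transforming growth factor beta and matrix, insulin and glucose, and the let-7, miR-17-92, miR-34, miR-15/16, Dlk1-Dio3, Sfmbt2 and X-linked miR-322, miR-503 and miR-450 families or clusters. Others covered mesenchymal, endothelial, blood, epithelial, striated muscle, neural and adipocyte cells, and hypoxia. A list with at least 3 members past the 50-count floor was described by its median log2 ratio, a bootstrap interval over members from 2000 draws, and its percentile among 10000 random lists of equal size matched on mean expression in 10 bins. Arms and neighbours within a list are not independent, so a percentile describes these 2 libraries. Arm usage was the share of a hairpin's counts on its 5p arm, with exact binomial (Clopper-Pearson) intervals, for hairpins with at least 50 counts over both arms in each library. The limit of 10 percentage points for an arm difference was chosen after the files were opened and before any arm share was computed.

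Named microRNAs followed a rule set before the data were examined. It took every mature form of miR-504, the 10 highest and 10 lowest ratios with at least 100 counts in a library and an interval excluding 1, the 5 most abundant of each library, and up to 4 members of each list with the highest mean CPM. Other microRNAs named in the text were chosen after their values were seen. Precursor genes were matched by name to GENCODE M21 on GRCm38, the assembly also called mm10, for 1884 of the 1909 names. Of the 356 microRNAs past the floor, 352 had a precursor gene and 313 had 1 only. A host gene is a gene on the same strand that contains the hairpin. Coordinates are those of the precursor hairpin, counted from 1.

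The computation was tested on simulated counts of 1909 microRNAs for the comparison of db/db with db/+. With 200 rates changed and 343 microRNAs past the floor, 96.2% of the 95% intervals held the simulated ratio. The size rule called 99.0% of the 4-fold and 3.0% of the 1.5-fold changes, and 0 unchanged microRNAs. For these values the simulated libraries differed by the set changes and counting error only. Variation between cultures was not simulated, so they give no rate of false calls for the measured libraries. Of 200 random lists with no shift, 7.0% fell outside the central 95%. The simulated microRNAs varied independently, so that value does not cover lists whose arms, neighbours or identical rows vary together.

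Alternatives set before the data were examined were 4 other scalings (TMM factors of edgeR 4.0.16, size factors of DESeq2 1.42.0, upper-quartile factors, and the total without the 10 most abundant microRNAs), floors of 10, 100 and no counts, a fold of 1.5, an interval beyond 2-fold, summed arms, and 0.1 or 5 counts added. Both packages were used here for scaling factors only. Alternatives chosen after seeing the data were the authors' deposited TMM reads, identical counts taken once, a trend on hairpin GC content removed, and the inflammation list without miR-504. Leaving out a library was not possible with 1 per group. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and R 4.3.3.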

Results

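Mature microRNAs were profiled in cultured aortic smooth muscle cells from diabetic db/db mice and from control db/+ mice, with 1 library per group and no replicates. The db/+ library held 25915732 microRNA counts over 881 detected microRNAs, and the db/db library 24295112 over 833. In total 967 microRNAs were detected in at least 1 library, 747 in both, and 356 reached 50 counts in at least 1. Every difference given here is between these 2 libraries, and a difference between genotypes could not be tested.

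The let-7 family, known for restraining proliferation, dominated both libraries, with 81.4% of counts in db/+ and 81.3% in db/db. The most abundant member, let-7c-5p, held 31.7% of counts in each and had a ratio of 1.001 (95% interval 0.9997 to 1.002). The next were let-7b-5p with a ratio of 1.06, let-7f-5p with 0.907 and let-7a-5p with 1.03. The fifth in both libraries was miR-140-3p, at 57246 CPM in db/+ and 69064 CPM in db/db, a ratio of 1.21 (1.20 to 1.21). The 10 most abundant microRNAs took 90.2% and 90.6% of counts.

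The series title names miR-504, and the comparison asked whether its level differed between diabetic and control cells. Both mature arms were higher in the db/db library. The 5p arm had 17 counts in db/+ (0.656 CPM) and 146 in db/db (6.01 CPM), a ratio of 9.16 with a 95% counting interval of 5.53 to 16.2 and a log2 ratio of 3.16. The 3p arm had 15 and 64 counts, a ratio of 4.55 (2.57 to 8.60) and a log2 ratio of 2.15. The precursor gene Mir504 lies on chromosome X from 59097658 to 59097736 on the minus strand of GRCm38, in an intron of Fgf13, a gene of the fibroblast growth factor homologous family. The level was low in absolute terms, and counting error was correspondingly wide. The endothelial list was also higher in the db/db library, with 8 counts over the whole list in db/+ and 71 in db/db, a ratio of 9.47 (4.55 to 22.8). All of these counts were on names of the miR-126 locus. Most of the db/db counts were on miR-126a-5p (2 and 58), and the interval of miR-126a-3p (5 and 13) included 1.

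Among the 356 microRNAs with at least 50 counts, 16 were at least 2-fold higher in the db/db library and 48 at least 2-fold lower. The highest ratio belonged to miR-10b-5p, which lies in an intron of Hoxd4 on chromosome 2 (74726070 to 74726137, plus strand) and had 18 counts in db/+ and 816 in db/db, a ratio of 48.4 (30.4 to 82.0). The lowest belonged to miR-217-5p, with 151 and 8 counts and a ratio of 0.0565 (0.0240 to 0.114). Most microRNAs differed little, with 222 of the 356 within 1.5-fold, and the median log2 ratio was -0.14. CPM values of the 2 libraries had a Spearman correlation of 0.937 across these microRNAs, which are not independent replicates.

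Several of the higher microRNAs were encoded on chromosome X besides miR-504. The ratio of miR-672-5p, from an intron of Nexmif, was 21.03 (9.94 to 53.3), on 7 and 138 counts. For miR-676-3p, from an intron of Eda, the ratio was 3.57 (3.07 to 4.17). Gabre, a GABA receptor subunit gene, hosts miR-224-5p and miR-452-5p in an intron, with ratios of 3.07 (2.501 to 3.78) and 2.44 (2.06 to 2.90). Higher autosomal microRNAs included miR-146a-5p at 5.06 (3.86 to 6.71), miR-181a-2-3p at 3.88 (3.12 to 4.86), miR-148a-3p at 2.43 (2.19 to 2.69) and miR-668-3p of the Dlk1-Dio3 locus at 2.28 (2.00 to 2.61).

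Among the lower microRNAs, miR-9-5p, best known from neural progenitors, had 347 counts in db/+ and 19 in db/db, a ratio of 0.0584 (0.0347 to 0.0926), and its 3p arm had a ratio of 0.0762. A similar ratio, 0.0603 (0.0469 to 0.0765), was measured for miR-196a-5p, whose hairpins lie in the Hox clusters, on 1273 and 72 counts, and miR-196a-1-3p had 0.107. The abundant miR-146b-5p, from an intron of Mfsd13a on chromosome 19, had 957 CPM in db/+ and 253 CPM in db/db, a ratio of 0.264 (0.257 to 0.271). The sister microRNAs miR-146a-5p and miR-146b-5p, both known as brakes on inflammatory signalling, thus lay on opposite sides. Their levels were unlike, as miR-146a-5p had only 2.51 CPM in db/+ and 12.7 CPM in db/db. Ratios of 0.282 for miR-3095-3p, 0.290 for miR-15a-5p, 0.2996 for miR-132-3p and 0.275 for miR-669l-5p were also among the 10 lowest with at least 100 counts in a library, each with an interval below 0.5.

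**Figure D1:**
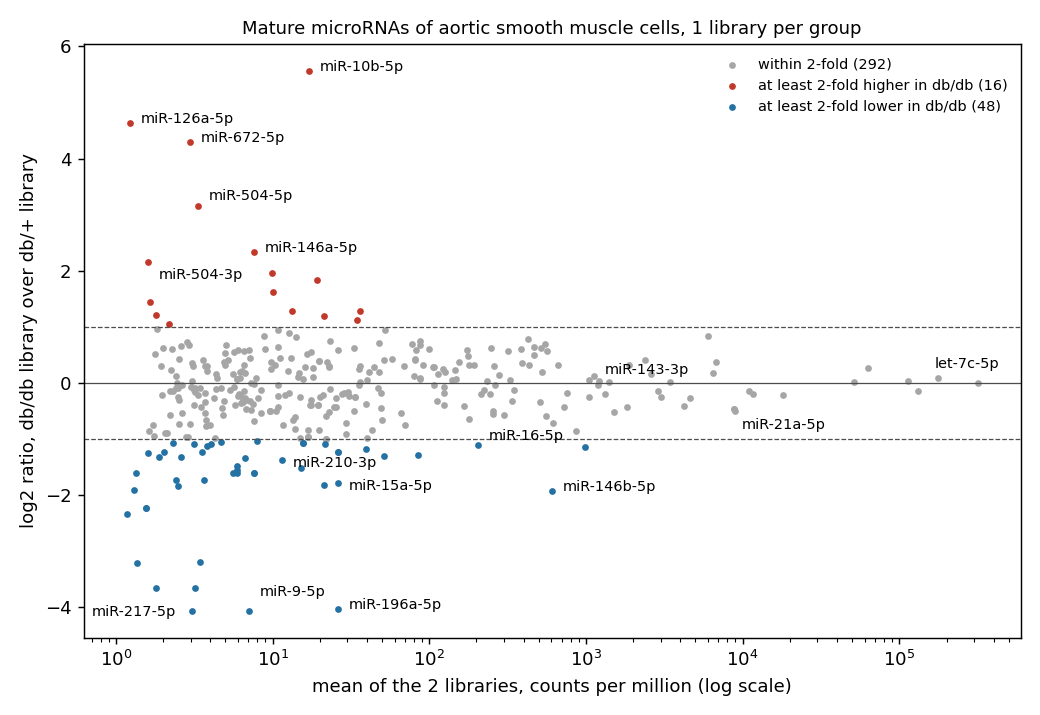
Each point is 1 of the 356 mature microRNAs with at least 50 counts in a library, with the mean CPM of the 2 libraries on a log axis and the log2 ratio of db/db over db/+ on the vertical axis, and dashed lines at 2-fold. The 16 red points are at least 2-fold higher in db/db and the 48 blue points at least 2-fold lower, with miR-504-5p at a log2 ratio of 3.16.

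Smooth muscle lists differed little between the libraries. Of the 5 contractile members past the floor 0 reached 2-fold (1, miR-1a-3p, under each of the 5 other scalings), and the median log2 ratio was -0.03, at percentile 30.9 of matched random lists. In it, miR-143-3p had a ratio of 0.971 (0.956 to 0.987), which lay above 1 under each of the 5 other scalings, and miR-145a-5p had 0.795 (0.771 to 0.819), while miR-1a-3p had 1.93 (1.78 to 2.09) and 2.01 to 2.06 under the other scalings. Growth and migration microRNAs had 3 ratios above 1 and 12 below, 0 at 2-fold and a median of -0.24 (percentile 18.5). Among them miR-21a-5p, often raised in injured vessels, had a ratio of 0.706 (0.702 to 0.710), miR-221-3p had 0.906 and miR-24-3p had 0.837.

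The vascular inflammation and diabetes list had 13 members past the floor, 4 of them at least 2-fold higher and 1 at least 2-fold lower. Its median was 0.32 (bootstrap interval -0.31 to 2.15), at percentile 97.6. The higher members were miR-126a-5p, both arms of miR-504 and miR-146a-5p, and the lower was miR-146b-5p. Abundant members were miR-125b-5p with a ratio of 1.01, miR-125a-5p with 1.25 and miR-181b-5p with 1.48. Since the study is titled for miR-504, the list is not independent evidence, and without its arms the median of the remaining 11 was 0.02, at percentile 60.3. The percentile was also inside the central range at a floor of 100 counts (85.0) and with a GC trend removed (93.6).

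Metabolic and matrix lists lay inside the range of random lists. The matrix list, which includes the collagen-targeting miR-29 family, had 4 ratios above 1 and 17 below, and a median of -0.24 (percentile 14.045). Of its 21 members, 4 were at least 2-fold lower (miR-29b-1-5p, miR-194-5p, miR-377-3p and miR-217-5p). The first had only 143 and 63 counts. The more abundant miR-29 arms had smaller differences, with miR-29a-3p at a ratio of 0.860 (0.857 to 0.864), miR-29b-3p at 0.702 and miR-29c-3p at 0.597. Ratios were 1.01 for miR-30a-5p and 0.880 for miR-30d-5p. The insulin and glucose list had 0 of 9 members at 2-fold and a median of -0.14 (percentile 27.2). In that list miR-103-3p, a regulator of insulin sensitivity, had a ratio of 0.750 (0.744 to 0.757), miR-320-3p had 0.908 and miR-26b-5p had 0.605. The let-7 list had a median of 0.00 (percentile 61.4).

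Members of the miR-15/16 list, named for a family that restrains cyclins, were lower as a group in the db/db library. The list took both arms of each hairpin, so its members include miR-322-3p, miR-16-1-3p (ratio 0.946) and miR-15b-3p (0.533). Of 10 members past the floor, 5 were at least 2-fold lower and 0 higher, and the median of -1.01 (bootstrap interval -1.60 to -0.08) lay at percentile 0.27. Ratios were 0.461 (0.442 to 0.480) for miR-16-5p, 0.405 (0.371 to 0.442) for miR-15b-5p and 0.290 (0.253 to 0.330) for miR-15a-5p, and near the floor 0.322 for miR-497a-5p and 0.188 for miR-195a-5p. The X-linked arms were mixed, with miR-322-3p at 1.27 (1.24 to 1.31), miR-503-5p at 1.04 (1.01 to 1.07) and miR-322-5p at 0.554 (0.485 to 0.633). The X-linked cluster of miR-322, miR-503 and miR-450 as a whole had 4 ratios above 1 and 4 below, and a median of -0.13 (percentile 56.1). The sign of that median depended on the setting. It was 0.05 at floors of 10, 100 and no counts and 0.21 with a GC trend removed, but -0.13 with identical counts taken once. Extremes of the cluster were miR-351-5p at 2.19 (1.98 to 2.43) and miR-450a-5p at 0.455 (0.329 to 0.623), with miR-351-3p at 1.55 and miR-450b-3p at 0.767.

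The growth-linked miR-17-92 clusters and paralogs had 4 of 12 members at least 2-fold lower and a median of -0.29 (percentile 18.3). The 4 were miR-17-5p (ratio 0.442), miR-18a-5p (0.422), miR-20a-5p (0.467) and miR-19b-3p (0.348), each with a precursor in Mir17hg on chromosome 14. Also with a precursor there, miR-92a-3p had a ratio of 1.02 (0.984 to 1.06), and miR-25-3p of the Mcm7 host had 1.33 (1.32 to 1.35), miR-25-5p 1.24 and miR-93-5p 0.953. The miR-34 and p53 list had 8 of 8 ratios below 1 (7 of 8 under 4 other scalings and 6 of 8 with upper-quartile factors) and a median of -0.68, at percentile 4.11 and so inside the central 95%. Its values included 0.699 (0.689 to 0.709) for miR-34c-5p, 0.505 for miR-34a-5p, 0.554 for miR-34b-5p and 0.979 for miR-192-5p, and 2 were at least 2-fold lower, miR-34c-3p (0.481) and miR-194-5p (0.396).

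Both large imprinted microRNA clusters stood apart from random lists, in opposite directions. In the Sfmbt2 intron cluster on chromosome 2, 13 of 28 members were at least 2-fold lower, 27 had ratios below 1, and the median of -0.97 (bootstrap interval -1.24 to -0.50) lay below all 10000 random lists. Names with identical counts are counted separately here, and taking them once left 19 members. With a trend on hairpin GC content removed, the Sfmbt2 median was -0.53 (percentile 0.03). The most abundant member, miR-669c-5p, was the exception with a ratio of 1.04 (1.02 to 1.06), while miR-669a-3p and miR-669o-3p, which had identical counts, had 0.424 (0.375 to 0.478) and miR-467a-3p had 0.744. In the Dlk1-Dio3 locus on chromosome 12, 35 of 59 members had ratios above 1 and 24 below, 1 was at least 2-fold higher (miR-668-3p) and 1 at least 2-fold lower (miR-377-3p, ratio 0.339), and the median of 0.27 (-0.03 to 0.30) lay at percentile 99.99. Its abundant members were miR-127-3p at 1.56 (1.52 to 1.61), miR-541-5p at 1.51, miR-382-5p at 1.48 and miR-433-3p at 1.41.

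**Figure D2:**
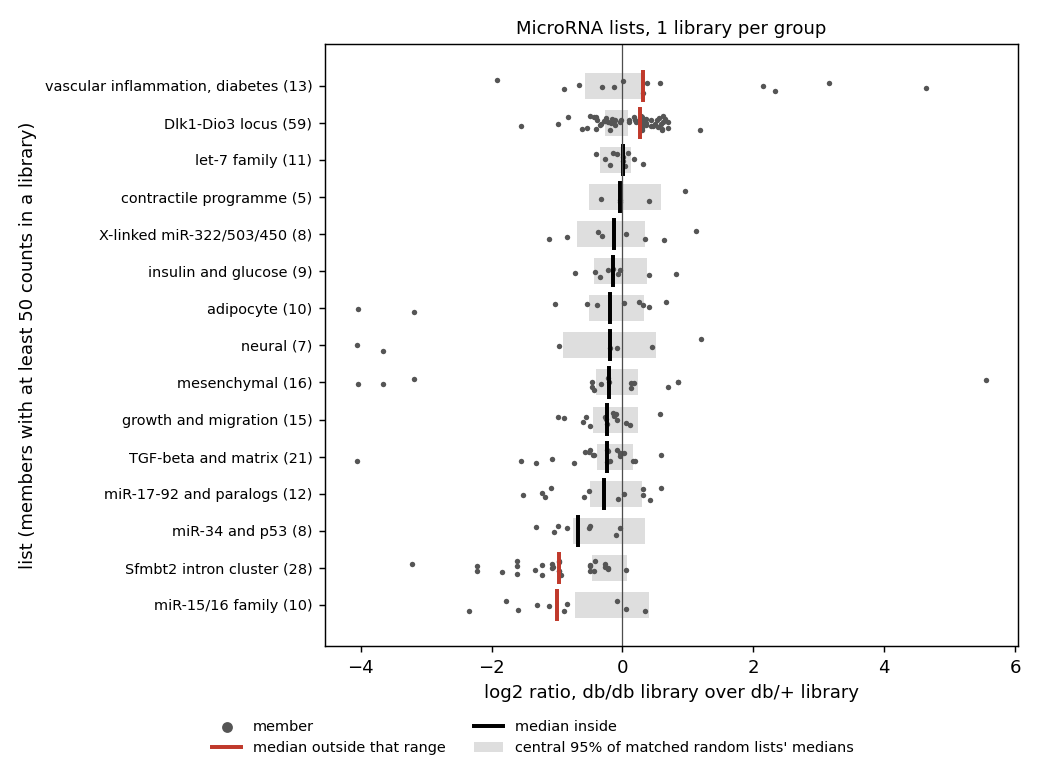
Each gray point is a list member's log2 ratio of db/db over db/+, each vertical bar is the list's median, and each gray band is the central 95% of medians of 10000 random lists matched on mean expression, with the number of members past the floor in parentheses. Medians of the miR-15/16 (-1.01) and Sfmbt2 (-0.97) lists lie below their bands, Dlk1-Dio3 (0.27) lies above, and the inflammation and diabetes list (0.32) lies at the edge.

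Endothelial, blood and epithelial microRNAs were rare, while those of the striated muscle, neural and adipocyte lists were more abundant. Endothelial members summed to 0.310 CPM in db/+ and 2.92 CPM in db/db, most of the latter from miR-126a-5p, which had 2 and 58 counts (ratio 30.9, interval 8.19 to 262), while miR-126a-3p had 5 and 13 counts (2.77, 0.928 to 9.94). Blood and immune members, with identical counts taken once, summed to 7.52 CPM in db/+ and 7.24 CPM in db/db (13.3 CPM in each as deposited), led by miR-486a-5p and miR-486b-5p, which shared the same 150 and 147 counts, and miR-451a had 17 and 14. Epithelial members summed to 0.730 and 1.23 CPM, with 0 of 16 past the floor and miR-200a-3p at 3 and 12 counts. Striated muscle members summed to 2509 and 2833 CPM, and miR-206-3p, a skeletal muscle microRNA, made up nearly all of it with a ratio of 1.12 (1.11 to 1.13). Other members were far lower, with 920 and 1664 counts for miR-1a-3p, 5 and 3 for miR-499-5p and 1 and 1 for miR-133a-3p. The sum thus reflects miR-206-3p and not the list as a whole.

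Neural, mesenchymal and adipocyte lists had medians inside the range of random lists. Neural members summed to 312 CPM in db/+ and 264.5 CPM in db/db, and had a median of -0.19 (percentile 46.2). Of 7 past the floor, both arms of miR-9 were at least 2-fold lower and miR-124-3p was higher, with 28 and 61 counts (ratio 2.32, 1.46 to 3.78), while miR-128-3p had 0.874, miR-7a-5p 0.943 and miR-7a-1-3p 0.506. For the mesenchymal list the median was -0.21 (percentile 19.4), yet of 16 members miR-10b-5p was at least 2-fold higher and miR-196a-5p, miR-196a-1-3p and miR-199b-5p lower, the last with 87 and 6 counts (ratio 0.0736, 0.0263 to 0.167). Its abundant members were miR-199a-3p and miR-199b-3p, which had identical counts, at 0.727 (0.723 to 0.732), miR-152-3p at 0.871 and miR-10a-5p at 1.80 (1.78 to 1.81). Adipocyte members summed to 519 and 512 CPM, and their median was -0.19 (percentile 28.3). It was also -0.19 at a floor of 100 counts, but 0.13 (percentile 80.2) at a floor of 10 and 0.25 (92.5) with no floor. Among the members, miR-365-2-5p had 1.25, miR-365-3p had 0.684, and miR-193a-5p (0.487) and both miR-196a forms were at least 2-fold lower. In the hypoxia list, both arms of the hypoxia-induced miR-210 were lower in the db/db library, miR-210-3p with 431 and 156 counts (ratio 0.386, 0.319 to 0.465) and miR-210-5p with 59 and 23 (0.416, 0.245 to 0.684).

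Arm usage was compared within each library and so does not depend on scaling. Of 204 hairpins, 196 had the same major arm in both libraries, and the 5p share differed by at least 10 percentage points in 20, of which 10 were lower and 10 higher in db/db. The most deeply counted of these was miR-23b, with a 5p share of 33.5% (95% interval 33.0 to 34.1) of 32364 counts in db/+ and 52.4% (51.8 to 52.9) of 31388 in db/db. The share for miR-106b was 64.9% (62.4 to 67.2) in db/+ and 46.3% (43.6 to 48.9) in db/db, and miR-574 had 41.7% and 56.3%. Intervals were apart in 12 of the 20 and in 53 of all 204. Hairpins were counted by name, and some names had nearly equal counts. For example, miR-299a (1104 counts in db/+ and 1016 in db/db) and miR-299b (1105 and 1018) are both among the 12. The number of distinct differences may therefore be smaller.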

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

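Tests with the deposited TMM reads, with a GC trend removed, with identical counts taken once and without miR-504 were chosen after the results were seen. The ratio of miR-504-5p was between 9.16 and 9.80 over all scalings, and its log2 ratio was 3.19 with 0.1 and 2.87 with 5 counts added. Scaling shifted all log2 ratios by 0.06 to 0.10, which exceeds the counting interval of abundant microRNAs. It put miR-143-3p above 1, at 1.03 (edgeR TMM, DESeq2 and deposited TMM), 1.04 (upper quartile) and 1.01 (without the 10 most abundant). The let-7 median was 0.088 with edgeR TMM and deposited TMM, 0.091 with DESeq2, 0.098 with upper-quartile factors and -0.19 with no floor. The Dlk1-Dio3 median was 0.36 with both TMM scalings, 0.37 with DESeq2 (0.365) and upper quartile (0.371), 0.33 without the 10 most abundant and 0.43 with the GC trend removed. Size-rule counts followed the threshold by construction: 46 higher and 91 lower at a floor of 10, 171 and 259 with no floor, and 48 and 86 at 1.5-fold. Arm differences numbered 35 at a floor of 10 and 71 with no floor. With no floor the miR-17-92 list lay at percentile 2.13. Of other alternative values, 201 answering a comparison did not move beyond their interval or 1.5-fold. Of those for single microRNAs, 207 left their counting interval, 9 of them crossing 1 (miR-93-5p and miR-192-5p, whose intervals included 1), and 238 stayed inside it. Apart from the scaling shift and thresholds, the cause of these movements was not tested. No paired analysis was possible because each group has 1 library, and leaving out a library left no comparison. Low counts limit microRNAs such as miR-126a-5p, with 2 counts in db/+.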

Other observations

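The tests on miR-504, on miR-10b and miR-196a, on whole miR-15/16 hairpins and on chromosome X were chosen after the results were seen, while those on GC content, shared copies and neighbouring precursors were written before their tested values, although the list medians and the correlation with GC content were already known. Further microRNAs differed in ways not yet described. All 4 arms of the miR-132/212 locus on chromosome 11 were lower in the db/db library, with ratios of 0.2996 for miR-132-3p, 0.297 (0.186 to 0.459) for miR-212-3p, 0.633 (0.540 to 0.741) for miR-212-5p, the major arm of its hairpin, and 0.598 (0.408 to 0.869) for miR-132-5p. The abundant miR-129-2-3p, from an intron of Mir670hg, had 1368 CPM in db/+ and 617 CPM in db/db, a ratio of 0.451 (0.443 to 0.460). The minor arm miR-140-5p had a ratio of 0.325 (0.243 to 0.429) beside 1.21 for the major arm miR-140-3p. The miR-155-5p ratio, another inflammation-linked microRNA, was 0.629 (0.579 to 0.682).

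For the higher level of miR-504 in the db/db library, scaling was argued against by a lower bound of the miR-504-5p ratio of at least 5.53 under every scaling run. Reads of another sequence on 1 arm were argued against by the 3p arm, whose lower bound was 2.57. Blood or immune cells were tested with the whole blood list, identical counts taken once, which had 195 counts in db/+ and 176 in db/db, and its interval allowed an increase of at most 1.40 CPM against at least 2.97 CPM for miR-504-5p. Nearly all of these counts were on miR-486 (5p arm 150 and 147) and miR-451a (17 and 14). The bound therefore covers cells that carry those microRNAs and cannot decide on blood or immune cells that lack them. Endothelial cells stay open. The whole endothelial list had a ratio of 9.47 (4.55 to 22.8), about that of miR-504-5p, but a like ratio is no evidence for such cells. Its 2.92 CPM in db/db (95% interval 2.28 to 3.69) lay below the 6.01 CPM of miR-504-5p (5.07 to 7.07). How much miR-504 endothelial cells carry beside miR-126 was not measured here, so these levels cannot decide. That list's counts came from the miR-126 locus alone, mostly from the arm miR-126a-5p. A genotype difference may also be an explanation, and with 1 library per group it stays open beside variation between cultures.

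Hox-linked microRNAs lay on opposite sides, with miR-10b-5p higher and miR-196a-5p lower in the db/db library. Miscounted miR-10a reads would keep 1 ratio to miR-10a, yet miR-10b-5p per miR-10a-5p read was 0.0160% in db/+ and 0.432% in db/db, 27.0 times higher with a lower bound of 16.9. Cultures from different stretches of the aorta cannot be told apart from genotype here. The Hox-cluster microRNA miR-196b-5p (exon of Hoxa9, chromosome 6) also differed, with a ratio of 1.79 (1.47 to 2.19), which either could give.

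Shifts of the Sfmbt2, miR-15/16 and Dlk1-Dio3 lists were set against a GC-dependent difference, as log2 ratios and hairpin GC content had a Spearman correlation of 0.239 across 352 microRNAs (0.126 without the Sfmbt2 list). With the trend removed, the Sfmbt2 median went from -0.97 to -0.53 (-0.84 to -0.22, percentile 0.03) and Dlk1-Dio3 stood at 0.43 (0.30 to 0.54, percentile 99.98), so GC is unlikely to be the whole cause, although only 12 other microRNAs had a GC content at or below the Sfmbt2 median. The miR-15/16 median went from -1.01 to -0.81 and stayed outside the range of random lists (percentile 0.12), but its bootstrap interval of -1.64 to 0.08 reached the random median of 0.01, so GC there was not excluded by the bound set beforehand. Identical counts taken once left a Sfmbt2 median of -0.98 over 19 members (percentile 0.05), against names with exactly equal counts as the cause. Near-identical copies may share only part of their reads, and such names stayed separate. Examples are miR-467a-3p (754 counts in db/+ and 526 in db/db) and miR-467d-3p (740 and 512). Sharing of that kind was therefore not tested. Lower whole hairpins were argued against for miR-322, with 2.30 times as many 3p reads per 5p read in db/db (2.007 to 2.63). The value for miR-16 was 2.03 (1.62 to 2.54), an interval that excludes 1, but its 2 copies share their 5p reads, so the question stays open there. It also stays open for miR-15a (1.15), with 16 and 5 counts on 3p. In miR-15b both arms were lower, and the value of 1.32 had an interval that included 1 (0.843 to 2.02). That fits a lower whole hairpin, but on 70 and 35 3p counts the interval overlapped that of miR-16. An equal fall of both arms was therefore not shown.

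A hypothesis that neighbouring precursors share transcription was tested on 80 same-strand pairs within 10 kb. Their median absolute difference in log2 ratio was 0.417, against 0.622 for random pairings (percentile 0.34), as the hypothesis predicts. Identical counts were taken once, but neighbours that share part of their reads or have like GC content could also have alike ratios. The test cannot tell these apart from shared transcription. Outside the Sfmbt2 and Dlk1-Dio3 lists, 33 pairs had 0.405 against 0.579, at percentile 4.63, a similar difference on fewer pairs that lay inside the central 95%.

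A second hypothesis concerned chromosome X, which held 6 of the 14 hairpins at least 2-fold higher in db/db, counting 1 arm per hairpin, and 23 of the 273 hairpins past the floor. Of 10000 random sets matched on expression, 7 held as many. The sets treated hairpins as independent, although miR-224 and miR-452, both among the 6, lie close together in Gabre. The number of sets that held as many may therefore be too low. An earlier count by mature microRNA, 8 of 16, was reached by 0 of 10000 sets, and was replaced because arms of a hairpin are not independent. A higher level of X-linked microRNAs as a whole stays open, since their median log2 ratio of 0.05 over 31 microRNAs lay at percentile 94.9 of random lists, and its bootstrap interval of -0.33 to 0.44 held the random median of -0.19. The criterion for this test was changed 2 times after its values had been seen, from a percentile to an upper bound of 2-fold and then to the random median. The X-linked excess was noticed in these data and may reflect a few loci or these particular cultures.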
